A study of Homo sapiens with 4 samples.

How the data were processed

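Gene expression was measured by RNA sequencing in 4 libraries of the human melanoma line A375, 2 with a control hairpin and 2 with a hairpin against CCDC50. The authors deposited 1 table of estimated counts, with 1 whole number per gene and library and no scaling to a common total. Trim Galore, HISAT2 and the genome build hg38 are named per the submitters' processing notes, without versions or roles. The counting tool, its strand setting and the annotation are not given in the sources used here. Genes are identified in the table by an Ensembl identifier paired with a symbol. Columns were matched to samples by name, and groups and replicate numbers came from the sample titles.

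The deposited values are treated as estimated counts already rounded by the authors, because the value 4 was more frequent than 3 in every library and about double the frequency of 5. In shCtrl replicate 1 these values occurred for 744 genes (value 3), 843 genes (value 4) and 395 genes (value 5). How this pattern arose is not stated in the sources used here and was not tested, so counts of whole reads are not excluded. A low value may rest on fewer reads than it shows. Without a stated strand setting, reads of a gene and of its antisense partner may be pooled, and a tool that estimates counts per transcript can shift reads between overlapping gene models.

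Of 67130 genes in the table, 28033 had a count in at least 1 library, and 18299 passed edgeR's filterByExpr at its default settings. All rows named a gene, and 24 tested entries share a symbol with another and were kept separate. Library sizes were scaled by the trimmed mean of M-values, with factors from 0.948 to 1.04. Groups were compared by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with no covariate and Benjamini-Hochberg adjustment over all tested genes, at a threshold of 0.05. The common dispersion was 0.0601, a biological coefficient of variation of 24.5%. Log2 differences are shCCDC50 minus shCtrl, their standard errors were derived from the F statistic, and intervals cover 95%. An exact permutation test of 2 against 2 libraries cannot reach 0.05, so none is given.

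The 32 gene lists, the genes to be named, the tests and most alternatives were fixed before the data were examined. The lists cover inflammasome, innate immune, autophagy and lysosomal genes, melanoma state, signalling, stress, cell cycle, growth and metabolism, markers of other cell types, and RNA quality. Each was tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over the 32 lists. The rule named CCDC50, then NLRP3, PYCARD, CASP1, IL1B, IL18, GSDMD and NEK7. It then took up to 8 genes per direction past the threshold with a mean of at least 5 CPM and groups that do not overlap, which gave RAB4B-EGLN2. From each called list with no member past the threshold it took the member with the smallest p. Other genes were named as examples, for their abundance, their p or a DESeq2 call, after their values were seen. Results for some genes are not reported here.

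Coordinates, transcript GC content and shared exons came from GENCODE release 29 on the same genome build. GC content was known for 98.5% of tested genes and coordinates for 98.6%. This annotation need not be the one used for counting.

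The alternatives fixed in advance were scaling by DESeq2 size factors or upper quartiles, no filter or a stricter filter (1 CPM in 2 libraries and a mean of 20 counts), DESeq2 1.42.0, limma-voom, the replicate number as a block, thinning to the smallest library, each library left out in turn, a threshold of 0.01, camera with an estimated correlation, and fry. Added after the data were seen were values divided by 4, an offset for each library's loess trend on GC content (span 0.3), the same with transcript length, summing of genes that share an exon on the same strand, camera with an estimated correlation and fry on the GC content offset, camera with an estimated correlation with each library left out, and camera with the estimated correlation preset. DESeq2 was run without the filter for edgeR. Figures were drawn with matplotlib.

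The procedure was tested on simulated counts for the 18299 genes, 2 libraries against 2. EdgeR recovered 8% of 50 genes changed 1.5-fold, 34% of 50 changed 2-fold, 98% of 50 changed 4-fold and 100% of 50 changed 8-fold, with 19 unchanged genes called. DESeq2 recovered 18%, 62%, 100% and 98% of the same sets, with 34 unchanged genes called. The false calls of both exceeded the nominal rate. All changed genes were simulated in the same set, and more calls loosen the Benjamini-Hochberg cutoff. These rates may therefore overstate recovery in the data, where edgeR called 1 gene. Genes were simulated independently of each other, which cannot test camera's error rate where members of a list vary together. A list shifted by -0.30 was called by camera (adjusted p = 2.33e-08) with 0 other lists called. It was also called with a simulated GC trend left in (adjusted p = 0.00285) and with the trend removed by the offset (adjusted p = 3.16e-07). Without a GC trend it was missed with an estimated correlation (adjusted p = 0.537) and with fry (adjusted p = 0.418), and called with the estimated correlation preset (adjusted p = 8.57e-13). That estimate was -0.00649, and negative estimates were preset as 0, so the last result covers only a list without correlation.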

Results

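RNA sequencing was used to profile A375 cells, an established human melanoma line, that had received a lentivirus encoding either a control short hairpin RNA (shCtrl) or a hairpin against CCDC50 (shCCDC50). A short hairpin RNA is processed in the cell into a small interfering RNA that lowers the transcript it matches. Cells were kept under puromycin selection for 7 days before RNA was collected. The series title describes CCDC50 as a protein that restrains the NLRP3 inflammasome through autophagy of NLRP3. NLRP3 is a cytosolic danger sensor which, with the adaptor PYCARD and the protease CASP1, drives maturation of the cytokines IL1B and IL18. The 4 libraries form 2 groups of 2. Total estimated counts were 53150185 and 53158261 in shCtrl replicates 1 and 2, and 39668864 and 48295633 in shCCDC50 replicates 1 and 2. The limit that a count of 0 allows, 3 counts, therefore lay between 0.0561 and 0.0727 CPM (counts scaled to a common library total), for counting error only.

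The libraries did not fall into their groups as a whole. Across genes, log2 CPM correlated at 0.974 between the shCtrl libraries and at 0.967 between the shCCDC50 libraries, and at 0.964 to 0.976 between libraries of different groups. The first principal component held 43.7% of the variance and set shCCDC50 replicate 1, at 68.3, apart from the other libraries, which lay between -40.8 and -6.25. As a check for a library deposited again, which covers counting error only, the chi-square per degree of freedom was 58.5 for the shCtrl pair and 53.4 for the shCCDC50 pair, against 35.0 to 106 for pairs across groups, so no pair held the same counts. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

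The first comparison concerned the targeted transcript. CCDC50 (ENSG00000152492; hg38 chromosome 3, 191329077 to 191398670, plus strand) was lower in both shCCDC50 libraries than in either shCtrl library. It measured 94.7 and 73.6 CPM in shCtrl replicates 1 and 2, and 25.4 and 28.5 CPM in shCCDC50 replicates 1 and 2. Group means were 84.2 ± 14.9 CPM and 26.9 ± 2.20 CPM (SD, n = 2 each), and the fitted level with the hairpin was 32.0% of control. The log2 difference was -1.64 (SE 0.20, 95% confidence interval -2.11 to -1.18). No library's CCDC50 level went against its label. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment over 18299 genes, CCDC50 did not pass the threshold (adjusted p = 0.153). DESeq2 gave nearly the same log2 difference, -1.65 (SE 0.21), with an adjusted p of 4.80e-11. CCDC50 also passed in edgeR's quasi-likelihood test without shCtrl replicate 2 and without either shCCDC50 library, but not without shCtrl replicate 1. Each of these fits leaves a group with 1 library, which is assumed to vary like the other group. They therefore do not strengthen the comparison of all libraries.

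**Figure D1:**
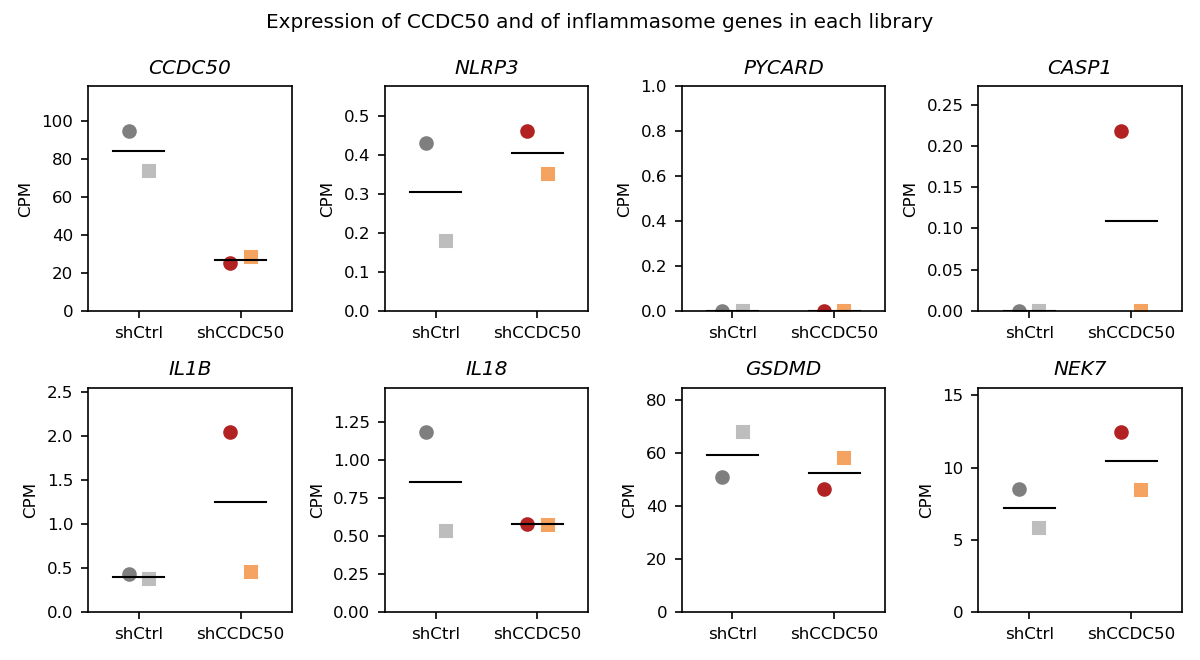
CPM of CCDC50 and of 7 inflammasome genes, with 1 panel and 1 linear axis from 0 per gene; circles are replicate 1, squares replicate 2, and black lines group means. CCDC50 lies at 73.6 to 94.7 CPM in shCtrl and 25.4 to 28.5 CPM in shCCDC50, NLRP3 and IL18 lie below 1.5 CPM, and PYCARD is at 0 in every library.

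The second comparison asked whether transcripts of the inflammasome differed with the hairpin. NLRP3 was low in every library, with 23 and 9 counts in shCtrl and 19 and 17 counts in shCCDC50, and its log2 difference of 0.40 (SE 0.78) had a confidence interval of -1.38 to 2.19. PYCARD had 0 counts in all 4 libraries, and CASP1 had 9 counts in shCCDC50 replicate 1 and 0 in the others, so neither could be tested. GSDMD, the pore-forming substrate of inflammatory caspases, was the most abundant of these genes, at 50.8 and 67.7 CPM in shCtrl and 46.5 and 58.0 CPM in shCCDC50 (log2 difference -0.18, SE 0.21). NEK7, a kinase that binds NLRP3, measured 8.57 and 5.82 CPM against 12.4 and 8.49 CPM (log2 difference 0.54, SE 0.30). IL18 stood at 1.18 and 0.536 CPM against 0.582 and 0.576 CPM (log2 difference -0.57, SE 0.58). IL1B stood at 0.430 and 0.377 CPM against 2.04 and 0.452 CPM (log2 difference 1.61, SE 0.73). The high IL1B value belonged to shCCDC50 replicate 1 alone, where IL1A, named here after its values were seen, also measured 3.03 CPM against 0.493 to 0.576 CPM elsewhere. Of the 30 genes listed for inflammasomes, 21 could be tested, 13 of them with a log2 difference above 0 and 8 below (median 0.18). Camera did not call this list (adjusted p = 0.516), and 0 members passed edgeR's quasi-likelihood test, whether adjusted over all genes or adjusted over the list alone. At an unadjusted p under 0.05 the count was also 0.

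Across the transcriptome, edgeR's quasi-likelihood test called 1 gene at an adjusted p under 0.05, with 0 genes higher. With 1 library left out it called 14 to 259 genes, 4 to 113 of them higher, in fits that leave a group with 1 library. The gene called with all libraries was RAB4B-EGLN2 (ENSG00000171570; chromosome 19, 40778242 to 40808418, plus strand), a readthrough gene model that spans the neighbours RAB4B and EGLN2. It held 818 and 582 counts in shCtrl and 2 and 9 counts in shCCDC50. It fell by 6.76 on the log2 scale (SE 0.48, adjusted p = 0.00994). RAB4B itself, a small GTPase of endosomal recycling, held 368 and 348 counts against 349 and 432 counts, a log2 difference of 0.33 (SE 0.23). EGLN2, a prolyl hydroxylase that acts on hypoxia-inducible factors, held 4786 and 5202 counts against 3698 and 4908 counts, a log2 difference of -0.02 (SE 0.18). RAB4B-EGLN2 shares exons on the same strand with 3 other counted genes, so its value depends on how reads were divided among them and is uncertain. With such genes summed into loci, 0 of 17105 were called by edgeR. At an unadjusted p under 0.05 there were 722, a smaller share than the 0.05 that chance gives. Limma-voom also called 0 genes, with RAB4B-EGLN2 at an adjusted p of 0.179.

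At an unadjusted p under 0.05 edgeR gave 733 genes, where 915 would be given by chance, and the groups did not overlap for 6571 genes, or 35.9%, where chance gives 33.3%. DESeq2, run on the 28033 genes with a count, called 32 genes, 9 higher and 23 lower, RAB4B-EGLN2 and CCDC50 among them. The genes of this paragraph were named after their values were seen. For 3 of the 32 almost all counts lay in 1 library: AC116366.2 (738 counts in shCtrl replicate 2, 0 elsewhere), PDCD6-AHRR (753 in shCCDC50 replicate 1, 0 elsewhere) and AC242842.3 (17709 in shCtrl replicate 1, 11 to 109 elsewhere). AC116366.2 and PDCD6-AHRR did not pass the filter for edgeR, which tested the other 30. Some genes called by DESeq2 share no exon on the same strand with another counted gene. Of these, ZMYND19, a zinc finger protein, was lower, at 31.5 and 26.9 CPM in shCCDC50 against 74.8 and 73.0 CPM in shCtrl (DESeq2 log2 difference -1.35, SE 0.20, adjusted p = 4.78e-08). MKNK2, a kinase that phosphorylates the translation factor EIF4E, stood at 25.8 and 22.5 CPM against 46.7 and 40.4 CPM (DESeq2 log2 difference -0.86, adjusted p = 0.0381). CHRDL1, a secreted antagonist of bone morphogenetic proteins, was higher, at 162 and 142 CPM against 72.1 and 96.9 CPM (DESeq2 log2 difference 0.84, adjusted p = 0.0381). SULF1, a heparan sulfate sulfatase, stood at 71.0 and 31.5 CPM against 21.2 and 20.9 CPM (DESeq2 log2 difference 1.27, adjusted p = 0.0294). In edgeR's test ZMYND19 had an adjusted p of 0.185, and MKNK2, CHRDL1 and SULF1 each had 0.875. VCX and VCX3A, called lower by DESeq2, are near-identical paralogs and are uncertain.

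Of 32 fixed gene lists, camera with a preset correlation called 3, all lower in shCCDC50 by small amounts: G2/M and mitosis, G1/S and DNA replication, and cytosolic ribosomal proteins. None of the 3 calls held when camera estimated the correlation among members (adjusted p = 0.809 for each with an estimated correlation), or with fry (adjusted p = 0.738, 0.668 and 0.808). Both tests have little power here, since they missed a simulated list shifted by -0.30 (adjusted p = 0.537 and 0.418). With camera and the estimated correlation preset, the 3 lists were not called (adjusted p = 0.517, 0.492 and 0.690). The simulated list was called (adjusted p = 8.57e-13), but its genes were drawn independently and its estimated correlation was -0.00649. Its call therefore shows no power at the 0.47, 0.26 and 0.57 estimated for the 3 lists. The 54 genes of G2/M and mitosis had a median log2 difference of -0.29, with 38 below 0 and 16 above (camera adjusted p = 5.02e-07 with the preset correlation, adjusted p = 0.809 with an estimated correlation). The 51 genes of G1/S and DNA replication had a median of -0.22, with 41 below 0 and 10 above (camera adjusted p = 0.000117 with the preset correlation, adjusted p = 0.809 with an estimated correlation). The 77 cytosolic ribosomal protein genes had a median of -0.14, with 60 below 0 and 17 above (camera adjusted p = 0.00156 with the preset correlation, adjusted p = 0.809 with an estimated correlation). In all 3 lists, 0 members passed edgeR's quasi-likelihood test, over all genes or adjusted over the list alone, and 13, 8 and 1 members had an unadjusted p under 0.05. The member with the smallest p was PLK1, the polo-like kinase of mitotic entry, in the first list, at 195 and 170.3 CPM in shCtrl against 87.8 and 125 CPM in shCCDC50 (log2 difference -0.78, SE 0.21, adjusted p = 0.875 in edgeR). In the second it was MCM2, a subunit of the replicative helicase, at 296 and 321 CPM against 184 and 222 CPM (log2 difference -0.60, SE 0.17, adjusted p = 0.875 in edgeR). In the ribosomal list it was RPL12, at 1892 and 2182 CPM against 1458 and 1723 CPM (log2 difference -0.36, SE 0.15, adjusted p = 0.875 in edgeR).

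Each of these calls depended on single libraries. In the G2/M list, PLK1, MYBL2 and AURKB were still lower in both shCCDC50 libraries than in either shCtrl library, while TOP2A and CDK1 overlapped. In the G1/S list, MCM2 and MCM5 were lower in this way, PCNA overlapped, and CCNE2 was higher. Apart from PLK1 and MCM2, these genes were picked after their values were seen. Members may vary together, so such genes are not independent support for a call. Relative to the mean of the 4 libraries, the median of the G2/M and mitosis genes was 0.33 in shCtrl replicate 1 and -0.07, -0.15 and -0.10 in shCtrl replicate 2 and shCCDC50 replicates 1 and 2. Without shCtrl replicate 1 that list had a median of -0.05 (camera adjusted p = 0.732). The G1/S and DNA replication genes lost their call without shCtrl replicate 1 (camera adjusted p = 0.493) and without shCCDC50 replicate 2 (0.140), a library in which short structured RNAs such as RN7SL1 stood apart, at 22.5 CPM against 3.42 to 4.03 CPM in the others. The ribosomal protein genes, at 0.19 in shCtrl replicate 2 and -0.16 in shCCDC50 replicate 1, lost theirs without either library (camera adjusted p = 0.826 and 0.334). The libraries also differed by GC content. Across 14041 genes, which are not independent replicates, the log2 difference between groups fell with transcript GC content (Spearman's rho -0.58). Over 10 equal bins of GC content, its median went from 0.24 in the lowest bin to -0.22 in the highest. Differences of single genes and list medians were not corrected for this trend unless the offset is named. NEK7, ATG4C and HSP90B1, given with positive differences, have low GC content (35.7%, 34.8% and 41.2%). Whether the trend adds to their differences was not tested. Among G2/M and mitosis genes, the 27 of higher GC content had a median of -0.42 and the 27 of lower GC content 0.04.

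**Figure D2:**
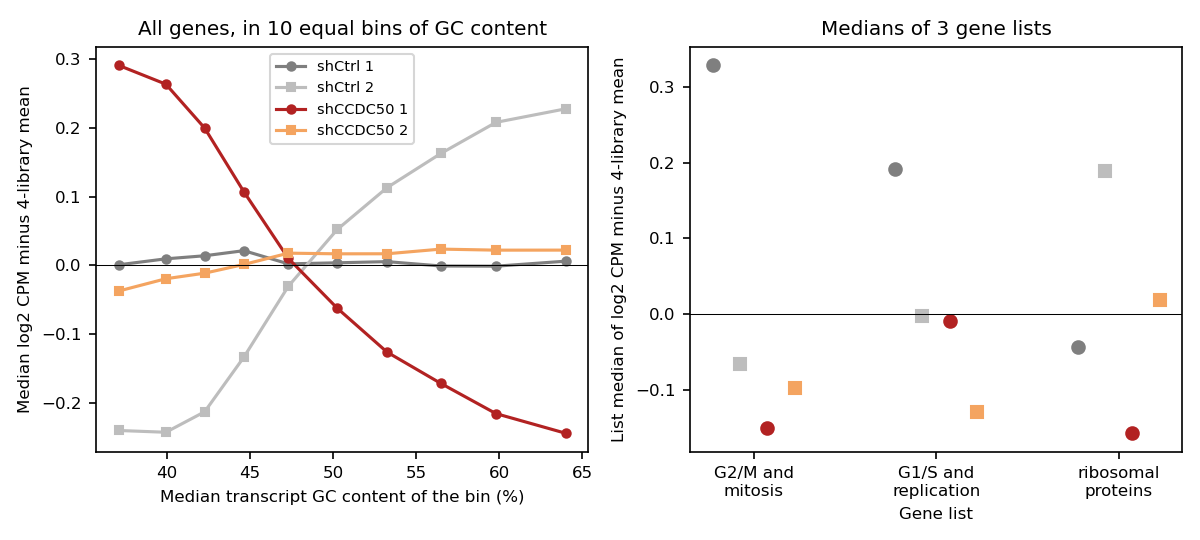
Left, median log2 CPM of each library minus the mean of the 4 libraries (vertical axis) in 10 equal bins of genes ordered by transcript GC content (horizontal axis, median percent of the bin), with lines joining the bins; right, the same quantity as a median over each of 3 gene lists, with circles for replicate 1, squares for replicate 2, greys for shCtrl, and red and orange for shCCDC50. shCtrl replicate 2 and shCCDC50 replicate 1 slope in opposite directions with GC content, and shCtrl replicate 1 stands apart at 0.33 for G2/M and mitosis genes.

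Genes of innate immune signalling were not called as groups by camera with all libraries, the default filter, the preset correlation and no GC content offset. The same settings apply to the lists in the next paragraphs. The stricter filter and the GC content offset each called more lists in total, as given below. The 46 tested interferon-stimulated genes had a median log2 difference of 0.13, with 28 above 0 and 18 below (adjusted p = 0.358). EIF2AK2, a kinase activated by double-stranded RNA, measured 57.1 and 39.6 CPM in shCtrl against 66.2 and 53.7 CPM in shCCDC50. IRF9, a transcription factor of interferon signalling, was the 1 member of any list that passed when edgeR's p-values were adjusted over the list alone (adjusted p = 0.0432). That adjustment does not cover the search over 32 lists, so 1 pass is weak evidence. IRF9 measured 17.4 and 11.8 CPM against 5.75 and 3.23 CPM (log2 difference -1.71, SE 0.34), with an edgeR adjusted p of 0.875 over all genes. DESeq2 called IRF9 over all genes (log2 difference -1.72, SE 0.35, adjusted p = 0.000846). The IRF9 value is uncertain because a longer gene model on the same strand covers it. The 21 genes of RIG-I-like receptor and STING signalling had a median of 0.08 (adjusted p = 0.458), and the 21 of antigen presentation by MHC class I a median of -0.08 (adjusted p = 0.684). The NF-kappa-B targets had a median of 0.01 and a mean of 0.17 over 31 genes (adjusted p = 0.957). Their smallest p belonged to BIRC3, an inhibitor of apoptosis, at 2.50 CPM in shCCDC50 replicate 1 and 0.411 to 0.843 CPM in the other libraries. The 23 cytokines and chemokines had a median of 0.12 while their mean, -0.02, and the direction of camera's test were negative (adjusted p = 0.957). The negative mean rests on CXCL5, at 0.224 and 0.397 CPM in shCtrl and 0 in both shCCDC50 libraries, without which the mean of the other 22 genes was 0.30. CXCL8 measured 25.7 CPM in shCCDC50 replicate 1 against 1.56 to 5.70 CPM in the other libraries, and CXCL3 2.62 CPM against 0.397 to 0.473 CPM. EIF2AK2, BIRC3, CXCL5, CXCL8 and CXCL3 were chosen as examples after their values were seen, as were the genes named in the next paragraphs.

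**Figure D3:**
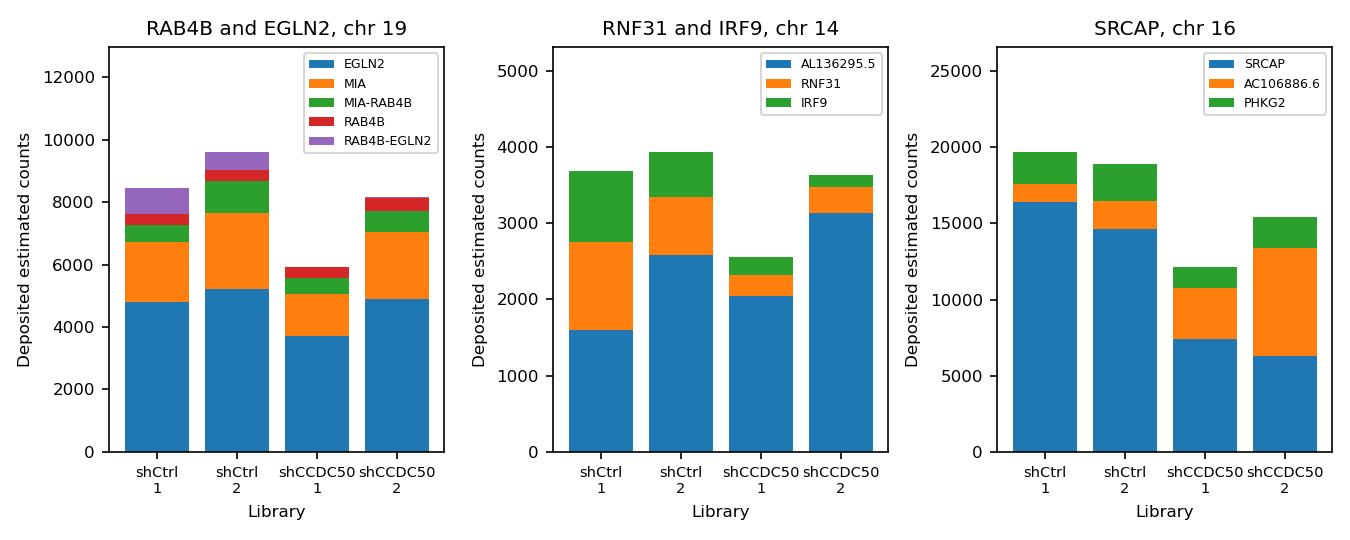
Deposited estimated counts (vertical axis, linear from 0) of overlapping gene models, stacked, in each of the 4 libraries (horizontal axis) at RAB4B and EGLN2, RNF31 and IRF9, and SRCAP, with 2 less abundant models of the SRCAP locus left out. IRF9 holds 932 and 596 counts in shCtrl and 237 and 157 in shCCDC50, the spanning model AL136295.5 holds 1596 and 2583 against 2044 and 3139, and RAB4B-EGLN2 makes up a small part of its stack.

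Autophagy and lysosomal genes were measured because of the role given to CCDC50. Of 48 autophagy genes, 29 had a log2 difference above 0 and 19 below, with a median of 0.10 that camera did not call (adjusted p = 0.280). SQSTM1, an autophagy receptor, measured 189.9 and 202 CPM in shCtrl against 182 and 179 CPM in shCCDC50. ATG4C, a protease that processes the ATG8 family, measured 4.94 and 4.53 CPM against 9.63 and 7.30 CPM (log2 difference 0.84, SE 0.26, adjusted p = 0.875 in edgeR). The 41 lysosomal genes had a median of -0.08 (camera adjusted p = 0.669). Among them, CTSS, a lysosomal cysteine protease, measured 1.46 and 1.87 CPM against 3.93 and 4.17 CPM (log2 difference 1.28, SE 0.31, adjusted p = 0.875 in edgeR).

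At the same settings, camera called none of the lists for melanoma state and signalling. The melanocyte differentiation programme had a median log2 difference of -0.11 over 24 genes (adjusted p = 0.686), and the dedifferentiated or invasive programme -0.10 over 34 genes (adjusted p = 0.0731). SOX10, a transcription factor of the melanocyte lineage, measured 1047 and 1517 CPM in shCtrl against 791 and 1279.8 CPM in shCCDC50. MAPK pathway output had a median of 0.03 (adjusted p = 0.957) and immediate early and stress-kinase genes -0.12 (adjusted p = 0.0731). The p53 targets had a median of 0.002 (adjusted p = 0.686) and apoptosis regulators 0.09 (adjusted p = 0.669). MYC targets in ribosome biogenesis had a median of -0.07 (adjusted p = 0.686).

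Stress and metabolism lists were likewise not called by camera. The median log2 difference was 0.04 for the unfolded protein response (adjusted p = 0.592), -0.07 for ATF4 targets (adjusted p = 0.358) and -0.07 for NRF2 targets (adjusted p = 0.352). It was 0.04 for heat shock genes, whose mean was -0.01 (adjusted p = 0.957), and -0.04 for glycolysis and hypoxia, whose mean was 0.01 (adjusted p = 0.962). Nuclear-encoded oxidative phosphorylation had a median of -0.05 over 76 genes (adjusted p = 0.333), cholesterol biosynthesis -0.11 (adjusted p = 0.297) and extracellular matrix and adhesion -0.03 (adjusted p = 0.581). HSP90B1, a chaperone of the endoplasmic reticulum, measured 2609.6 and 2542 CPM in shCtrl against 3460.5 and 3105 CPM in shCCDC50 (log2 difference 0.35, SE 0.13, adjusted p = 0.875 in edgeR).

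Markers of other cell types and of RNA quality gave no call either. Medians were -0.18 over 11 fibroblast markers (camera adjusted p = 0.114), -0.36 over 9 epithelial and keratinocyte markers (0.114) and 0.18 over 5 immune cell markers (0.516). Replication-dependent histones had a median of 0.23 (camera adjusted p = 0.358), and nuclear-retained and small non-coding RNAs 0.12 (0.110). Within the latter list shCCDC50 replicate 2 stood apart on short structured RNAs. RN7SL1 and RN7SL2, RNAs of the signal recognition particle, measured 22.5 and 22.2 CPM there, against 3.42 to 4.03 CPM and 6.17 to 6.96 CPM in the other libraries. RN7SK, a regulator of transcription elongation, measured 15.5 CPM against 2.64 to 5.42 CPM, and the small nucleolar RNA SNORD3A 1.44 CPM against 0.131 to 0.242 CPM. The non-coding gene FP671120.7, outside the lists, measured 26.4 CPM in that library against 4.73 to 8.61 CPM. Mitochondrially encoded mRNAs had a median of -0.12 (camera adjusted p = 0.288), and mitochondrial transcripts made up 6.28% and 8.50% of counts in shCtrl and 6.82% and 7.54% in shCCDC50.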

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

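The GC content and length offsets, the division by 4, the summing of overlapping genes, and an estimated correlation or fry combined with another change were chosen after the data were seen. The count of genes past the threshold was 1 under other scalings, either filter, thinning, the 0.01 threshold, division by 4 and the GC content offset. It was 32 with the DESeq2 Wald test (9 higher, 23 lower), 0 with limma-voom, 0 with the GC content and length offset and 0 with overlapping genes summed. The cause was not tested, except that summing changes what is counted. Leaving out 1 library gave 14 genes (4 higher; without shCtrl replicate 1), 19 (8 higher; without shCtrl replicate 2), 127 (49 higher; without shCCDC50 replicate 1) and 259 (113 higher; without shCCDC50 replicate 2), a range of 14 to 259. These fits leave a group with 1 library, which is assumed to vary like the other group. RAB4B-EGLN2 missed the threshold with limma-voom (0.179), the GC content and length offset (0.0681) and overlapping genes summed (0.879), and was called in all fits that left out a library.

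The log2 difference of CCDC50 was -1.65 with DESeq2, where it passed, and ranged from -1.81 to -1.45 when a library was left out. Its edgeR adjusted p ranged from 0.0610 to 0.225 in the other alternatives that kept all libraries. With the replicate number as a block, edgeR called 3 genes (2 higher, 1 lower) and camera 4 lists. The samples share only a number, and their deviations from the group means correlated at 0.12.

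The count of called lists was 5 under the stricter filter, 0 with an estimated correlation, 0 with fry, 6 with the GC content offset, 5 with the GC content and length offset, and 3 to 7 when a library was left out. Adjusted p for the G2/M, G1/S and ribosomal lists was 0.809 each with an estimated correlation, and 0.738, 0.668 and 0.808 with fry. With the GC content offset it was 0.9503 each with an estimated correlation, and 0.872, 0.872 and 0.896 with fry. When a library was left out at the preset correlation, adjusted p ranged from 1.41e-19 to 0.732, from 4.28e-08 to 0.493 and from 5.65e-07 to 0.826 for these lists. At an estimated correlation it was 0.848 each without shCtrl replicate 1, 0.941, 0.941 and 0.979 without shCtrl replicate 2, 0.9001, 0.890 and 0.918 without shCCDC50 replicate 1, and 0.904, 0.921 and 0.904 without shCCDC50 replicate 2, with 0 lists called. Glycolysis and hypoxia turned to a call of higher without shCtrl replicate 2 (0.000411; up to 0.994 without another library), and NF-kappa-B targets to a call of lower without shCCDC50 replicate 1 (0.0216; up to 0.682), both at the preset correlation. With an estimated correlation these fits gave 0.941 and 0.890, on 1 residual degree of freedom, which leaves little power. With the value estimated in the same fit preset, both lists were again called. For NF-kappa-B targets that estimate was -0.024 and was preset as 0, so no correlation was allowed for. Neither list was called with all libraries under any setting of the correlation. The cause was not tested. NLRP3 rested on 9 to 23 counts per library and IL18 on 24 to 63, so counting error adds to their intervals. The IL1B interval also covers a spread of 84 against 22 counts between the shCCDC50 libraries. CASP1 and PYCARD did not pass the filter, and why PYCARD is at 0 was not tested.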

Other observations

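The GC content offset, the summed loci of RAB4B-EGLN2 and of IRF9 with RNF31, and the count of called genes without overlaps were chosen after the results they bear on were seen. Camera with an estimated correlation was fixed in advance as an alternative, but presetting the estimated value as a test of an explanation was chosen after its result was seen. Several genes called by DESeq2 formed reciprocal pairs with an overlapping gene model. CATSPERZ, a testis gene, held 77 and 116 counts in shCtrl and 1 and 0 in shCCDC50, while the readthrough model KCNK4-TEX40 over the same exons held 0 and 0 against 68 and 65. NPIPP1 held 1079 and 764 counts against 174 and 246, while PKD1P6-NPIPP1 held 605 and 848 against 1335 and 1271. SRCAP, the ATPase of a chromatin remodelling complex, held 16387 and 14666 counts against 7410 and 6279, while the overlapping model AC106886.6 held 1183 and 1836 against 3350 and 7096. STRA6LP held 703 and 467 counts against 95 and 90, while CCDC180, which DESeq2 did not call, held 9 and 100 against 539 and 377.

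These pairs may come from reads being divided differently between overlapping gene models. Of 29 genes called by DESeq2 that have coordinates, 16 (55.2%) share an exon on the same strand with another counted gene, against a median of 13.8% and a highest value of 44.8% in 10000 random sets matched on expression. In 5 of 12 loci the lower called genes were a large enough part for their fall alone to move the locus sum by at least 2 SE, and in all 5 the sum lay within 2 SE of no change and over 2 SE from that fall. The loci of CATSPERZ, NPIPP1, SRCAP and STRA6LP among these are the pairs picked above for opposite changes, so their sums partly restate that choice. The SRCAP sum, -0.28 (SE 0.15) where the fall alone would give -0.71, also leaves room for a partial fall. For IRF9 and RNF31 the summed log2 difference was -0.11 (SE 0.19), where their fall alone would give -0.50. For RAB4B-EGLN2 the sum was -0.16 (SE 0.18) and its fall alone would give -0.11, so a change of the transcript and a shift of reads cannot be told apart, because EGLN2 and MIA hold most of the counts; an effect of the hairpin on splicing or readthrough was not tested.

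Overlap on the same strand, in the annotation used here, does not account for every call. Of the 29 called genes with coordinates, 13 share no exon on the same strand with another counted gene, CCDC50, ZMYND19 and CHRDL1 among them. Overlap with genes on the opposite strand was not examined. For CCDC50 the hairpin named in the design accounts for a lower level. For ZMYND19 and CHRDL1, an effect of CCDC50 loss, an effect of the hairpin on other transcripts and a false call stay open and were not tested. Neither passed edgeR's test with all libraries. DESeq2 called 34 unchanged genes in the simulated counts and 32 genes in the data. The simulated set also held changed genes, whose calls loosen the Benjamini-Hochberg cutoff. These counts are therefore not comparable and give no share of false calls in the data.

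The lower G2/M, G1/S and ribosomal lists, as called with the preset correlation, are not explained by the GC content trend between libraries as the whole cause. With the trend removed and the preset correlation kept, camera's adjusted p was 6.25e-19 for G2/M (median log2 difference -0.34), 3.48e-08 for G1/S (median -0.19) and 6.06e-06 for ribosomal proteins (median -0.16). With the trend removed and an estimated correlation it was 0.9503 for each, and 0.461, 0.461 and 0.766 with the value estimated in that fit preset, so the offset does not secure the calls. A candidate explanation is that members vary together from library to library and that single libraries decide the calls. The estimated correlation was 0.47, 0.26 and 0.57, and with these values preset the adjusted p was 0.517, 0.492 and 0.690. The values rest on 2 residual degrees of freedom and are imprecise. The highest adjusted p with a library left out, at the 0.01 preset, was 0.732 and 0.493 (both without shCtrl replicate 1) and 0.826 (without shCtrl replicate 2). An effect of CCDC50 loss on proliferation stays open and untested.

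The 4 libraries can be split into pairs in 3 ways, too few for a share under 0.05. As small a camera p was given to the G2/M list by 2 of the 3 splits (adjusted p = 5.02e-07 for the real split, 4.42e-07 for the smallest other), to the G1/S list by 1 (0.000117 and 0.00170) and to the ribosomal list by 2 (0.00156 and 6.43e-07). Replicates 1 against replicates 2 gave 6 genes, 1572 genes at an unadjusted p under 0.05 and 13 lists at the preset correlation. The real split gave 1, 733 and 3, so a split that ignores the groups gave more calls. Whether the samples hold a structure other than the groups was not tested. Libraries of the same number share only that number, and which libraries drive this split was not tested. The remaining split gave 3 genes, 235 genes at an unadjusted p under 0.05 and 5 lists.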
